A study of Mus musculus with 4 samples.

How the data were processed

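Kupffer cells were isolated, per the labels' protocols, by collagenase perfusion of the livers of male C57BL/6 mice aged 8 weeks and density centrifugation on Percoll, plated in medium with 10% serum, and treated in medium with 0.1% serum for 24 h with 200 nM maresin 1 or ethanol vehicle. Total RNA was labelled with Cy3 and hybridised to one-colour Agilent arrays. The 4 samples fall into 2 groups of 2 by their treatment label. The labels give each group a replicate 1 and a replicate 2 without saying what a number marks.

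The scanner output deposited for each array holds linear intensity values. Per the file headers and the submitters' processing notes, the authors extracted them with Agilent Feature Extraction 11.0.1.1, which subtracts the background and corrects spatial trends within an array, with no normalization between arrays. All 4 arrays were on 1 slide, vehicle at the first pair of positions and maresin 1 at the next pair, so position and group cannot be told apart. Each array held 62976 spots, of which 59305 were not controls, and 56605 distinct probes. No spot was saturated (0 on each array), and 94 to 123 spots per array carried an outlier mark. The headers mark the negative-control net signal of vehicle replicate 2 (41.4, against 37.2 to 38.9 on the others) for evaluation.

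The deposited value table of the series holds log2 values. No label states its scale or filter, so they were found from the values: each column correlated with log2 of the processed signal of the same array with r = 1, the sorted columns differed by at most 0.00217, as after quantile normalization, every listed probe was well above background on all 4 arrays, and each column's median was 9.07. It was used only as an alternative.

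The values analysed were log2 of the processed signal minus the array's 75th percentile over non-control spots. Control spots and spots with an outlier mark were left out, and spots of 1 probe were averaged. A probe was kept if well above background on both arrays of at least 1 group (31128 probes). Probes were named through the RefSeq accession in the scanner output, without version, in a table of RefSeq genes of assembly GRCm38.p6, used for names only: 32994 probes (58.3%) matched 1 symbol each and 23611 kept the identifier of the array's design. Each gene was represented by its brightest kept probe, which gave 24067 genes, 14496 of them with a RefSeq symbol. Among called genes with several kept probes (1309), 16 had a probe called in the opposite direction. A gene not well above background on any array of a group has only a bound there, computed from the mean of the brighter group against the higher of the lowest signal well above background and the probe's own signal, and written as "at least N-fold"; this was so for 196 called genes in the vehicle and 121 in the maresin 1 group.

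Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), without a replicate term. The fit had 2.27 prior degrees of freedom and a prior SD of 0.0738 on the log2 scale. Gene lists were tested with camera (preset correlation 0.01, two-sided, at least 5 measured members, Benjamini-Hochberg over the 28 lists), with camera at an estimated correlation and with fry. Scanner output was read with the data.table package 1.17.8 and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on simulated data for this comparison (24050 genes, 50 changed at each size): 4% of genes changed by 0.5 on the log2 scale were recovered, 78% at 1, 84% at 2 and 98% at 3, and 3 of 135 calls were false. In the data 24% of genes passed, which makes the adjusted threshold easier to reach, so these recovery rates do not carry over. The simulated noise was independent between arrays and does not address replicates that may be technical. A shifted list was called with the preset correlation, while its adjusted p with an estimated correlation was 0.0819. A list that misses the threshold with an estimated correlation is therefore not argued against by that test.

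The groups, test, gene lists, named-gene rule and alternatives were fixed before the data were examined, apart from the exceptions given here. Named genes were, in each direction, the 12 called genes with the largest log2 difference and groups that did not overlap, leaving out names that are accessions, clone or predicted-gene identifiers; 17 genes of macrophage activation, Kupffer cell identity and lipid mediators named in every case; up to 4 members of each list with the smallest unadjusted p; and the most abundant member of each cell type list. Normexp background correction (offset 50) was planned on the mean spot signal, a column not used here, and was run on the median spot signal. The alternatives were quantile normalization, normexp with quantile normalization, the authors' value table, no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, a variance trend, spots with outlier marks kept, a replicate block, and each array left out in turn. With an array left out, 1 group holds a single array, assumed to vary like the other group. A slide term was not run, as there was only 1 slide. Values of single genes for 2 list members are not reported here, although counts and list tests include them. Coordinates were not analysed here.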

Results

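RNA from primary mouse Kupffer cells, the resident macrophages of the liver, was measured on 4 one-colour arrays. The cells came from 8-week-old male C57BL/6 mice and had been cultured for 24 h in medium with 0.1% serum. The medium held either maresin 1 at 200 nM or its ethanol vehicle, and each group had 2 arrays. Maresin 1 is a lipid mediator that macrophages make from docosahexaenoic acid and is known for promoting the resolution of inflammation. Between 54.4% and 55.6% of the 56605 probes were well above background on each array. The 75th percentile of the processed signal was 961 and 988 on the vehicle arrays and 946 and 847 on the maresin 1 arrays. Across probes, which are not independent replicates, the arrays of a group correlated with r = 0.9986 (vehicle) and r = 0.9983 (maresin 1), and arrays of different groups with r between 0.9912 and 0.9923. The number of arrays limits the precision of every value.

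The comparison asks which transcripts differ between Kupffer cell cultures given maresin 1 and cultures given vehicle. Genes of alternative (M2-type) macrophage activation were among the most strongly raised. Arg1, which encodes arginase 1, rose 8.42-fold, with a log2 difference of 3.07 ± 0.05 (SE of the limma fit, n = 2 arrays per group, as for all differences that follow). Chil3, a chitinase-like lectin, rose by 3.80 ± 0.11 on the log2 scale, and the chemokines Ccl17 and Ccl8 rose by 3.79 ± 0.08 and 3.70 ± 0.08. The formyl peptide receptors Fpr1 (-2.61 ± 0.12) and Fpr2 (-2.37 ± 0.10), which sense bacterial and host peptides, fell. Rora, a nuclear receptor gene, rose 2.34-fold (1.23 ± 0.08), from a level of 1.44 ± 0.02 to 2.66 ± 0.12 (SD, n = 2; log2 relative to the array's 75th percentile). Alox12, a lipoxygenase gene, rose by 0.76 ± 0.06, whereas Alox15 (-0.23 ± 0.08, adjusted p = 0.116) and Alox5 (-0.01 ± 0.09, adjusted p = 0.952) did not pass the test. Lgr6, which encodes a receptor for maresin 1, was not well above background on any array.

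**Figure D1:**
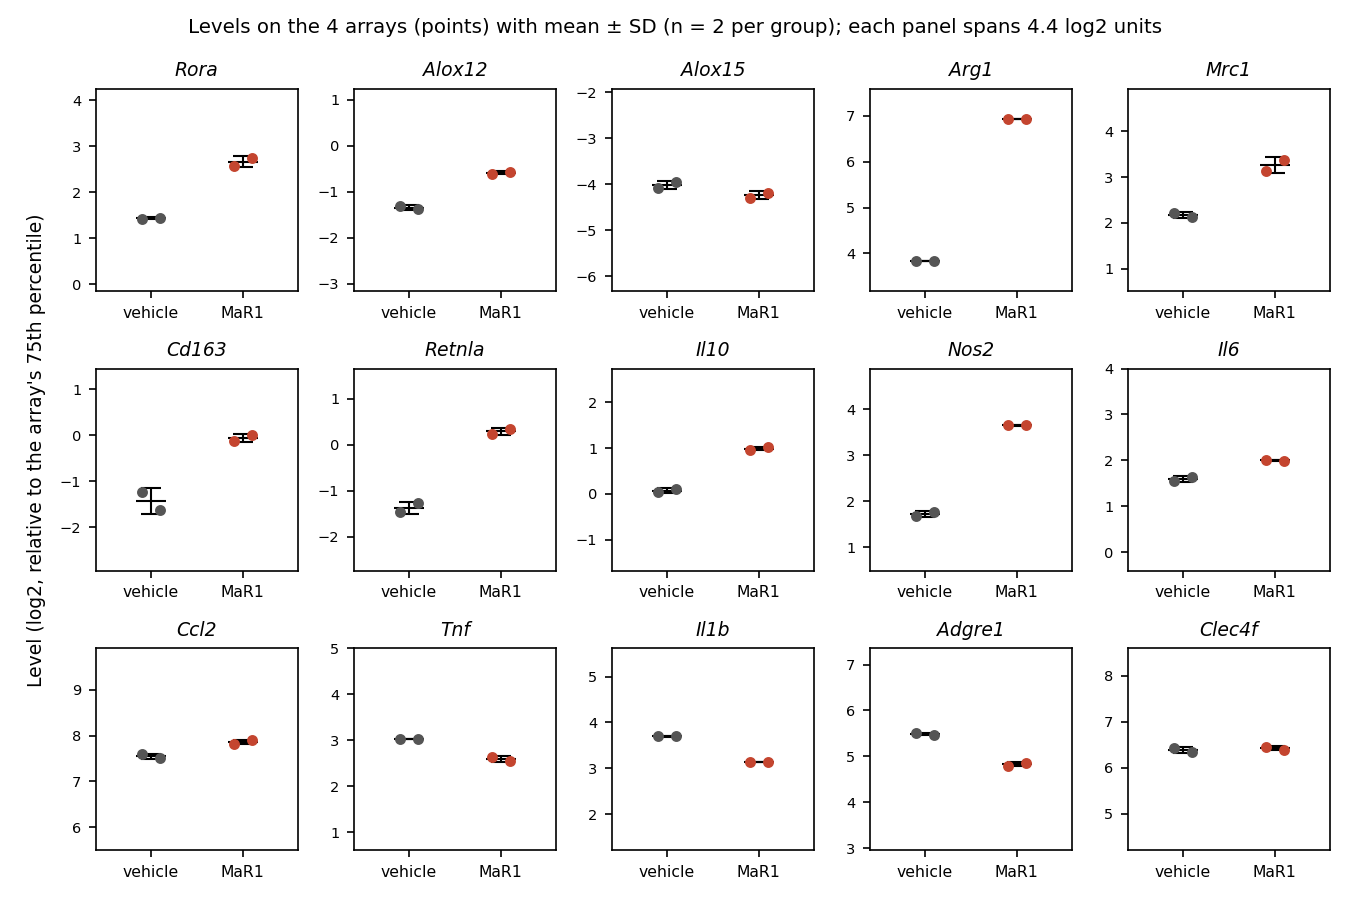
Levels of 15 genes on the 4 arrays (points, log2 relative to the 75th percentile of each array) with mean ± SD of vehicle and maresin 1 (MaR1) groups (n = 2). Every panel spans the same height on the log2 scale, so that the rise of Arg1 by 3.07 stands beside the value of 0.04 for Clec4f.

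Of the 24067 genes tested, 2700 were higher and 3068 lower with maresin 1 by limma's moderated test after Benjamini-Hochberg adjustment. With genes not well above background in a group taken at their bound, differences of at least 2-fold were found for 474 of the higher and 227 of the lower genes, and differences of at least 4-fold for 73 and 11. By fitted difference, which is no bound for such genes, 553 genes were at least 2-fold higher and 272 at least 2-fold lower at an unadjusted p under 0.05. At that p, 9792 genes passed regardless of size, where chance alone would give 1203. The labels do not say whether the arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical, and group also coincided with array position on the single slide. Leaving out 1 array gave 959 higher and 800 lower genes (without vehicle replicate 1), 1083 and 840 (without vehicle replicate 2), 1207 and 1162 (without maresin 1 replicate 1) or 882 and 668 (without maresin 1 replicate 2), with 288 to 429 at least 2-fold lower by fitted difference at an unadjusted p under 0.05. Among the other counts that moved by over 1.5 times were 1087 and 972 with no filter on dim probes (31.8% of the calls kept), 4524 and 4672 with a variance trend, and 276 and 87 at least 2-fold by fitted difference at an unadjusted p under 0.05 with normexp on the median signal and quantile normalization together.

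**Figure D2:**
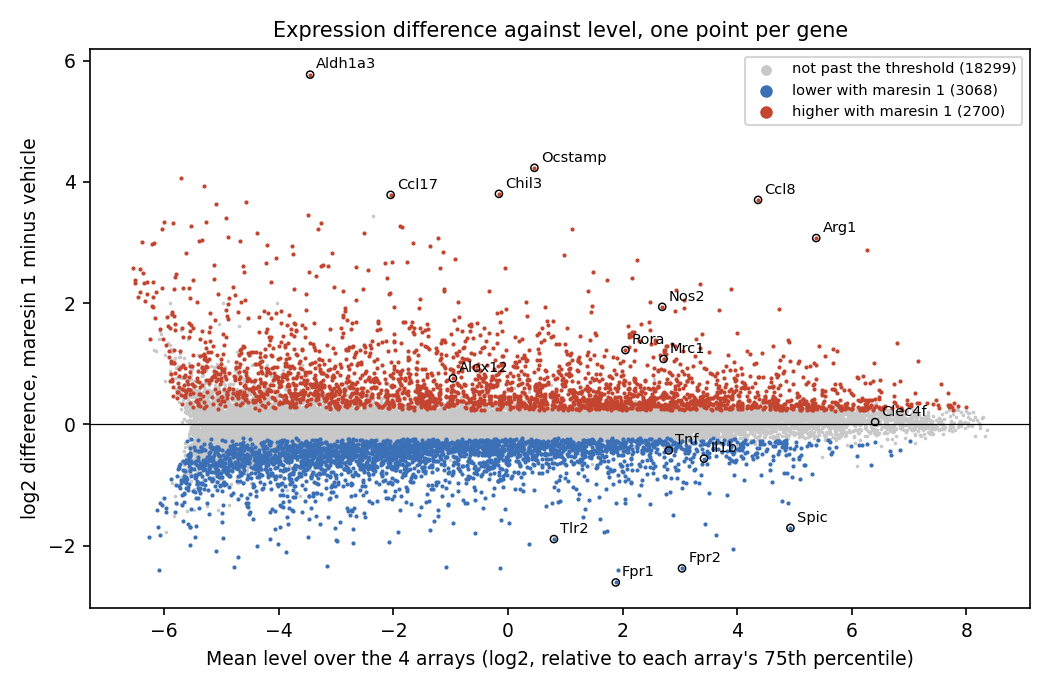
Log2 difference (maresin 1 minus vehicle) against the mean level over the 4 arrays (log2 relative to each array's 75th percentile), 1 point per gene, with 2700 higher genes in red and 3068 lower genes in blue. Fitted differences of genes not well above background in a group, such as Aldh1a3, stand for at least the bound given in the text, and with each gene at its brightest probe the largest decrease was that of Fpr1 (-2.61).

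Ranked by fitted difference, which is no bound for dim genes, the 12 named genes with the largest increases were led by Aldh1a3. Its product, a retinaldehyde dehydrogenase, makes retinoic acid. Aldh1a3 was at least 31.9-fold higher (adjusted p = 0.00225) and not well above background on either vehicle array. Ocstamp, needed for the fusion of osteoclasts and macrophage giant cells, rose by 4.23 ± 0.09 on the log2 scale, and the chemoattractant receptor gene Gpr33 by 3.46 ± 0.08. The other genes with only a bound were Plcb1 (at least 7.10-fold higher), Il31ra (at least 5.08-fold), Tafa3 (at least 4.85-fold), the secreted phospholipase gene Pla2g5 (at least 4.68-fold), Clcn1 (at least 3.89-fold) and Plppr5 (at least 2.35-fold). At their other probes, also not well above background on either vehicle array, the fitted values of Plcb1 and Il31ra were 1.83 ± 0.20 and 2.59 ± 0.18 on the log2 scale. The value of Plcb1 lies below its bound, which therefore holds for the brightest probe only. The calls of Plcb1 and Clcn1 were lost without either maresin 1 array, with adjusted p up to 0.0788 and 0.102. Among the largest fitted decreases, Klra2 (-2.41 ± 0.07), Adgb (-2.37 ± 0.10) and Dnajc22 (-2.33 ± 0.06) fell. Clec4n, which encodes a fungal-sensing lectin, fell by 2.06 ± 0.09 on the log2 scale. Pcdhac2 (-2.01 ± 0.15), Zfp811 (-1.98 ± 0.10) and Pnoc (-1.97 ± 0.10) followed, each gene taken at its brightest probe. At their other probes the values of Pcdhac2 and Klra2 were -3.32 ± 0.16 and -1.81 ± 0.06. Igfbp1, Scel and Abca9 were at least 4.34-fold, 3.21-fold and 1.80-fold lower, being not well above background on either maresin 1 array, and the call of Abca9 was lost without either vehicle array (adjusted p up to 0.0869).

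Genes of the alternative activation (M2-type) list rose as a group. Of its 25 measured members, 19 rose, 2 fell and 4 did not pass, and the median log2 difference was 1.20. Adjusted over the list alone, 20 rose and 3 fell. The list was higher than other genes by camera (adjusted p = 2.42e-09), but did not pass with an estimated correlation (adjusted p = 0.371). The latter test also missed the shifted list of the simulated data (adjusted p = 0.0819), so for this and the following lists it cannot decide. Pdcd1lg2, which encodes the checkpoint ligand PD-L2, rose by 3.22 ± 0.06, the eotaxin gene Ccl24 by 2.87 ± 0.07, Retnla by 1.67 ± 0.09, the mannose receptor gene Mrc1 by 1.08 ± 0.10 and Il10 by 0.91 ± 0.06. The 2 members that fell were the scavenger receptor genes Stab1 (-0.88 ± 0.06) and Msr1 (-0.75 ± 0.06). Cd163 rose by 1.38 ± 0.15 at its brightest probe and had a value of 0.12 at its other probe, and its call was lost without either maresin 1 array (adjusted p up to 0.0687). In all, 15 of the 19 members that rose kept their call whichever of the 4 arrays was left out. Of the 27 listed genes, 7 are also on other lists. Markers of dendritic cells were higher in the same arrays (7 of 14 rose, median 0.42). Without Ccl22, which is on both lists, 6 of 13 rose, with a median of 0.365.

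Members of the pro-inflammatory (M1-type) list went both ways. Of 28 measured members, 11 rose, 7 fell and 10 did not pass (12 and 7 adjusted over the list alone). The list as a whole did not pass by camera (adjusted p = 0.0654 and adjusted p = 0.415 with an estimated correlation), but was higher by fry (0.0104). Nos2, the inducible nitric oxide synthase gene, rose 3.83-fold (1.94 ± 0.06), and the monocyte chemoattractant gene Ccl7 rose by 1.34 ± 0.06. Among the called members Fpr2 fell most (-2.37 ± 0.10). Tlr2, a receptor for bacterial lipoproteins, fell by 1.89 ± 0.06 on the log2 scale. The cytokine genes Il1b (-0.56 ± 0.05) and Tnf (-0.43 ± 0.06) fell, while Il6 (0.41 ± 0.06) and Ccl2 (0.30 ± 0.06) rose. The calls of Tnf, Il6 and Ccl2 were lost without any 1 of the 4 arrays (adjusted p up to 0.0928, 0.103 and 0.168), those of all 3 with no filter on dim probes, that of Ccl2 also with quantile normalization and in the authors' value table, and that of Il1b without either vehicle array or maresin 1 replicate 2 (up to 0.0548). Of the list's members, 7 of the 11 higher and 2 of the 7 lower kept their call whichever of the 4 arrays was left out. Without vehicle replicate 2 the list itself passed (adjusted p = 0.0446), as it did with no filter on dim probes (0.00283).

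Clock genes and lipid mediator genes also changed in both directions. On the circadian clock and ROR/REV-ERB list, 5 of 15 measured members rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.323 and adjusted p = 0.501 with an estimated correlation). Besides Rora, the repressor genes Nfil3 (1.15 ± 0.06) and Nr1d1 (0.87 ± 0.06), the latter encoding REV-ERB alpha, and Bhlhe40 (0.76 ± 0.05) rose, and these 4 kept their calls whichever array was left out. None of the 4 members that fell did so. On the lipoxygenase, cyclooxygenase and lipid mediator receptors list, 5 of 23 measured members rose and 7 fell (the same counts adjusted over the list alone, camera adjusted p = 0.797 and adjusted p = 0.840 with an estimated correlation), with a median of 0.00 and a mean of -0.20. The largest called decrease was that of Fpr2 (-2.37 ± 0.10), which is also on the M1-type list. Alox5ap (-1.31 ± 0.08), whose product assists leukotriene synthesis, and Hpgd (-1.07 ± 0.06), which breaks down prostaglandins, fell. The cyclooxygenase gene Ptgs1 rose by 0.93 ± 0.06. On this list, 2 of the 5 higher and 6 of the 7 lower members kept their call whichever of the 4 arrays was left out.

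Kupffer cell identity genes changed in both directions, and as a list they were lower by fry (adjusted p = 0.0103) but did not pass by camera. Clec4f, a lectin gene restricted to Kupffer cells, was bright on all arrays, with levels of 6.39 ± 0.06 and 6.43 ± 0.05 (SD, n = 2) and a difference of 0.04 ± 0.07 that did not pass (adjusted p = 0.693). Spic, which encodes a transcription factor of iron-recycling macrophages, fell by 1.71 ± 0.05 on the log2 scale. The iron exporter gene Slc40a1 (-0.82 ± 0.08) and Adgre1 (-0.67 ± 0.06), a macrophage surface marker gene, fell too. Of 24 measured members of the Kupffer cell identity list, 5 rose, 6 fell and 13 did not pass (6 and 8 adjusted over the list alone), and camera gave adjusted p = 0.603 (adjusted p = 0.680 with an estimated correlation), with a median of 0.01 and a mean of -0.12. On the efferocytosis and scavenger receptors list, 7 of 27 rose and 6 fell (11 and 9 adjusted over the list alone), among them Itgb3 (1.08 ± 0.06) and Gas6 (-0.67 ± 0.06). Its median (0.10) and camera's direction were positive and its mean (-0.04) negative, and it did not pass (adjusted p = 0.797 and adjusted p = 0.840 with an estimated correlation). Without any 1 of the 4 arrays, 0 of the 5 higher and 4 of the 6 lower identity genes kept their limma call in every case, and 1 of 7 and 5 of 6 did on the efferocytosis list.

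Antigen presentation and stress-related lists were higher. Of 14 measured members of the MHC class II presentation list, 6 rose and 8 did not pass (9 rose adjusted over the list alone, camera adjusted p = 0.00105 and adjusted p = 0.371 with an estimated correlation). The members with the smallest p were H2-Oa (1.57 ± 0.09), H2-DMb2 (1.46 ± 0.15), Ifi30 (0.67 ± 0.07) and H2-DMb1 (0.49 ± 0.06), genes of antigen processing or of peptide loading and its control. The classical chain genes H2-Aa (0.19) and H2-Ab1 (0.02), named after their values were seen, did not pass. On the heat shock list, 6 of 16 rose and 10 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000421 and adjusted p = 0.415 with an estimated correlation). Examples were Hspa1b at 0.89 ± 0.07 and Hspa1a at 0.78 ± 0.06. On the unfolded protein and integrated stress response list, 11 of 26 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00274 and adjusted p = 0.371 with an estimated correlation). Psat1, a serine synthesis gene, rose by 1.42 ± 0.08 and the stress-induced transcription factor gene Atf3 by 1.05 ± 0.07. On the hypoxia and glycolysis list, 11 of 27 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00105 and adjusted p = 0.371 with an estimated correlation), led by the vasodilator peptide gene Adm (1.49 ± 0.06), with Pfkp (0.81 ± 0.06) and the lactate exporter gene Slc16a3 (0.67 ± 0.05). The members that rose and kept their call whichever of the 4 arrays was left out numbered 2 of 6 (MHC class II), 2 of 6 (heat shock), 2 of 11 (unfolded protein) and 4 of 11 (hypoxia). In the same arrays, 7 of 14 markers of dendritic cells (median 0.42) and 4 of 10 of B cells (median 0.32) rose, 2 cell types that also present antigen. The call of Ifi30 was lost without maresin 1 replicate 2 (adjusted p = 0.054) and that of H2-DMb1 without any 1 of the 4 arrays (up to 0.0677).

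On the interferon response list, 9 of 28 rose and 19 did not pass (11 rose adjusted over the list alone, camera adjusted p = 0.0045 and adjusted p = 0.415 with an estimated correlation). Examples were Cmpk2 at 0.56 ± 0.07 and Gbp2 at 0.53 ± 0.07. None of the 9 kept its limma call whichever array was left out, with adjusted p up to 0.0737 for Cmpk2 (lost without vehicle replicate 1 or either maresin 1 array) and 0.0759 for Gbp2 (without any 1 of the 4 arrays). Camera's adjusted p was 0.355 with normexp on the median signal and quantile normalization, 0.451 with quantile normalization alone and 0.241 in the authors' value table. On the proliferation list, 10 of 26 rose and 4 fell (12 and 4 adjusted over the list alone). By camera the list did not pass (adjusted p = 0.0654 and adjusted p = 0.415 with an estimated correlation). The replication licensing genes Mcm5 (0.65 ± 0.07), Mcm7 (0.51 ± 0.06) and Mcm2 (0.42 ± 0.06) rose and the mitotic kinase gene Plk1 fell (-0.46 ± 0.07), but none of the list's calls held without every array in turn. The call of Mcm5 was lost without either maresin 1 array (adjusted p up to 0.0561), and those of Mcm7, Mcm2 and Plk1 without any 1 of the 4 arrays (up to 0.0674, 0.0837 and 0.0965). The proliferation list itself passed with normexp on the median signal and quantile normalization (0.0187), quantile normalization alone (0.0296), the authors' value table (0.0329), no filter on dim probes (0.000582) and without maresin 1 replicate 2 (0.0321).

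Genes of the antioxidant and NRF2-type list were lower as a group. Of 26 measured members, 9 fell, 1 rose and 16 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.00304 and adjusted p = 0.371 with an estimated correlation), and the median log2 difference was -0.20. The catalase gene Cat (-0.95 ± 0.07), Gpx2 (-0.80 ± 0.07) and Gstm1 (-0.77 ± 0.06) fell, whereas Sod3 rose by 0.59 ± 0.06. These 3 decreases kept their call whichever array was left out, the other 6 and the rise of Sod3 did not (adjusted p of Sod3 up to 0.0542 without either vehicle array or maresin 1 replicate 2), and with no filter on dim probes the list did not pass (0.0509). Markers of hepatocytes (median -0.27) and of stellate cells (median -0.34) were lower in the same arrays.

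Lipid metabolism lists did not pass as groups by camera. Fry called the fatty acid oxidation (adjusted p = 0.0382) and cholesterol biosynthesis (0.0433) lists lower. On the LXR targets and lipid handling list, 4 of 23 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.977 and adjusted p = 0.990 with an estimated correlation). Examples were Fabp4, a fatty acid carrier gene, at 1.29 ± 0.07 and Lpl, the lipoprotein lipase gene, at -0.83 ± 0.06. Its median was -0.04 while camera's direction was up. Leaving out each of the 4 arrays in turn, 1 of the 4 higher and 1 of the 3 lower members kept their call throughout. On the fatty acid oxidation and PPAR list, 1 of 25 rose and 5 fell (the same counts adjusted over the list alone, camera adjusted p = 0.111 and adjusted p = 0.501 with an estimated correlation). An example was Angptl4 at -1.03 ± 0.12, a call lost without maresin 1 replicate 2 (adjusted p = 0.0627). None of the list's 6 calls was kept whichever array was left out. This list passed with normexp on the median signal and quantile normalization (0.0196), quantile normalization alone (0.0296) and the authors' value table (0.0251). On the cholesterol biosynthesis list, 1 of 23 rose and 2 fell by limma (0 and 0 adjusted over the list alone, 8 in all at an unadjusted p under 0.05, camera adjusted p = 0.411 and adjusted p = 0.596 with an estimated correlation), the 3 being Insig1 (0.35), Sqle (-0.26) and Tm7sf2 (-0.45), all lost without any 1 of the 4 arrays (adjusted p up to 0.149, 0.180 and 0.118). On the lysosome and autophagy list, 3 of 28 rose and 5 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.950 and adjusted p = 0.978 with an estimated correlation), and Atp6v0d2, a proton pump subunit gene, rose by 1.01 ± 0.07. The median was -0.04 and the mean 0.00, and 1 of the 3 higher and 0 of the 5 lower members kept their limma call whichever array was left out.

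On the matrix and growth factors list, 10 of 24 rose and 6 fell (12 and 8 adjusted over the list alone). By camera the list did not pass (adjusted p = 0.193 and adjusted p = 0.495 with an estimated correlation), except with no filter on dim probes (0.0055). The collagenase gene Mmp13 rose 5.35-fold (2.42 ± 0.13) and Thbs1, which encodes the TGF-beta activator thrombospondin 1, by 1.01 ± 0.07. The collagenase gene Mmp8 (-1.53 ± 0.08) and the hepatocyte growth factor gene Hgf (-0.80 ± 0.05, with a value of -1.56 ± 0.10 at its other probe) fell. Of these, 5 of the 10 higher and 2 of the 6 lower members kept their call whichever of the 4 arrays was left out.

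**Figure D3:**
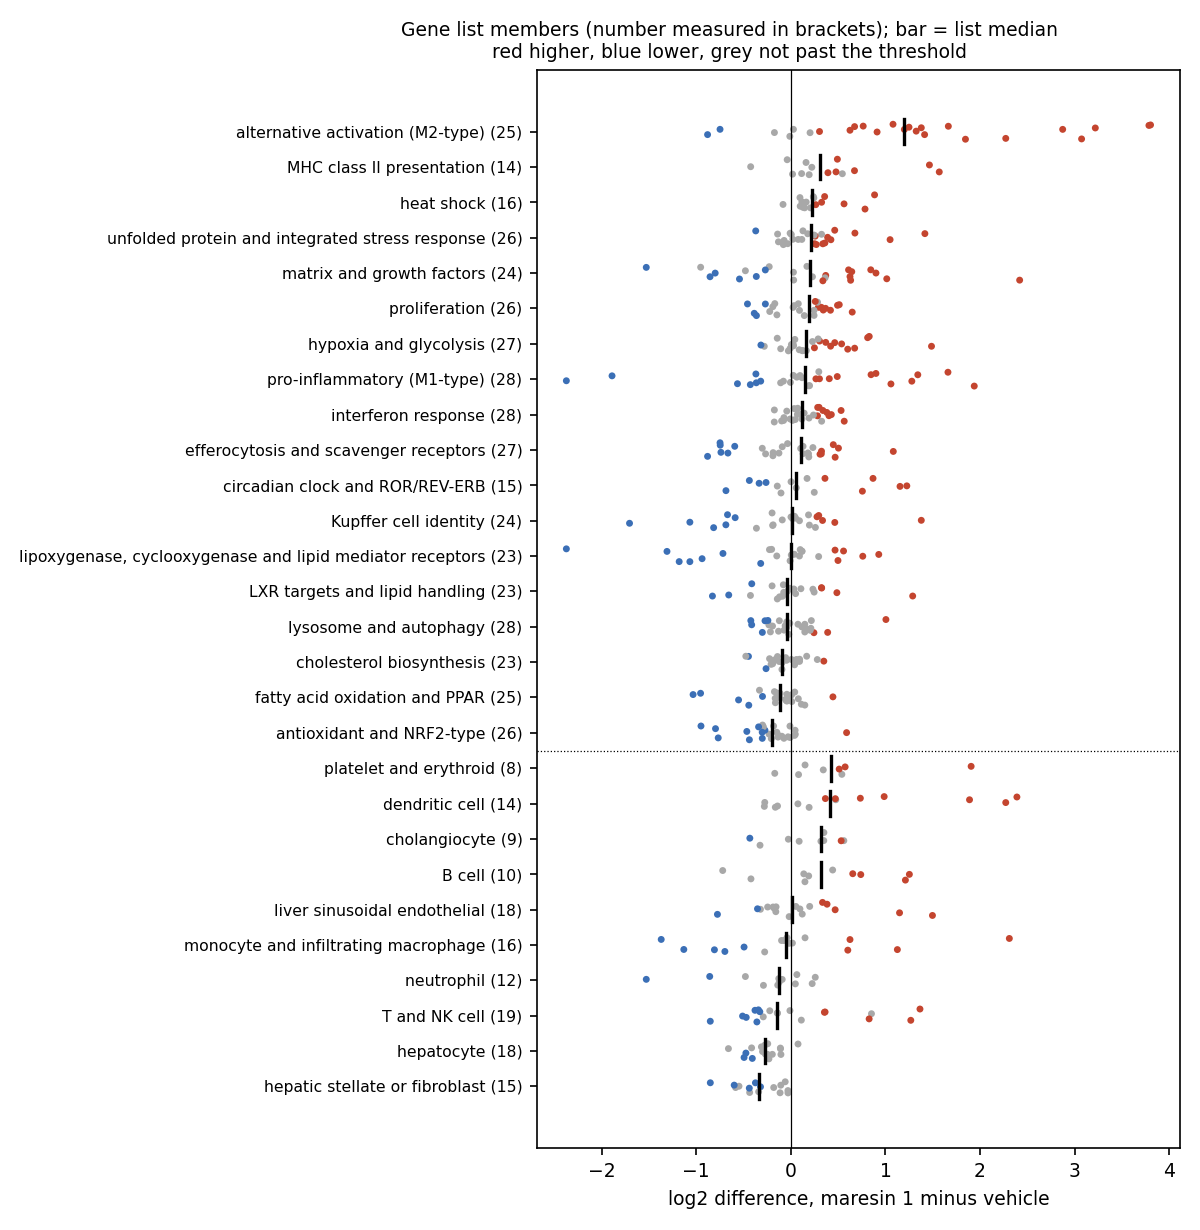
Log2 difference (maresin 1 minus vehicle) of each measured member of the 28 gene lists, with pathway lists above the dotted line and cell type markers below it; points are red for higher, blue for lower and grey for genes that did not pass, and bars are list medians. The M2-type list has the highest median (1.20) and the stellate list the lowest (-0.34).

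Markers of other liver and blood cells were detected in the cultures and differed between the groups. Some were about as bright as Kupffer cell genes. With vehicle and maresin 1, the endothelial marker Egfl7 had levels of 6.30 and 6.39 and the stellate marker Acta2 5.20 and 5.14. Clec4f had 6.39 and 6.43. The most abundant B cell marker, Cd22, was dimmer (2.22 and 2.37). Which cells held these transcripts was not tested, so all values are those of the whole cultures. On the dendritic cell list, 7 of 14 measured markers rose and 7 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00411 and adjusted p = 0.371 with an estimated correlation). These included Itgax, which encodes CD11c (2.39 ± 0.08), Ccl22 (2.27 ± 0.12), Batf3 (1.89 ± 0.06) and Clec9a (0.99 ± 0.06), and the median of 0.42 became 0.30 with dim markers at their bounds. These 4 of the 7 kept their call whichever array was left out, and the other 3 did not. B cell markers were higher (4 of 10 rose, 6 did not pass, 4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0378 and adjusted p = 0.501 with an estimated correlation). Ms4a1 had a value of 1.21 ± 0.09, and 1 of the 4 kept its call whichever array was left out. By camera the B cell list did not pass without vehicle replicate 1 or maresin 1 replicate 1, or with a replicate block (adjusted p = 0.0877). Nor did the list pass by fry (0.0518). The platelet and erythroid list was higher too (3 of 8 rose, 5 did not pass, 4 rose adjusted over the list alone, camera adjusted p = 0.00615 and adjusted p = 0.415 with an estimated correlation). The 3 were the carbonic anhydrase gene Car2 (1.91 ± 0.05), Alas2 (0.51 ± 0.06) and the haemoglobin gene Hba-a1 (0.57 ± 0.08). No platelet gene was among them. The call of Hba-a1 was lost without vehicle replicate 1 or either maresin 1 array (adjusted p up to 0.075). Of these 3, only Car2 kept its call whichever array was left out, and Car2 is also among the genes of osteoclast function given below.

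Hepatocyte markers were lower, with 3 of 18 falling and 15 not passing (the same count adjusted over the list alone, camera adjusted p = 0.00274 and adjusted p = 0.475 with an estimated correlation) and a median of -0.27. The 3 were Hp (-0.49 ± 0.08), Apoc3 (-0.48 ± 0.08, with a value of 0.13 at another probe) and Ttr (-0.41 ± 0.06), all lost without any 1 of the 4 arrays (adjusted p up to 0.106, 0.115 and 0.104), and the list did not pass with no filter on dim probes (0.22). Markers of hepatic stellate or fibroblast cells were lower as well (5 of 15 fell, 10 did not pass, 6 fell adjusted over the list alone, camera adjusted p = 0.0032 and adjusted p = 0.371 with an estimated correlation). Pdgfra had a value of -0.85 ± 0.08 and was the 1 of the 5 that kept its call whichever array was left out. The stellate list did not pass with no filter on dim probes (0.0509). The remaining cell type lists did not pass by camera. By fry, the neutrophil list was lower (adjusted p = 0.0103) and the sinusoidal endothelial list higher (0.0451). T and NK cell markers had 5 of 19 higher and 7 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.629 and adjusted p = 0.705 with an estimated correlation; median -0.14, mean 0.06). Examples were Gzma at 1.36 ± 0.09 and Thy1 at -0.85 ± 0.06, and 3 of the 5 higher and 1 of the 7 lower markers kept their call whichever array was left out. Monocyte and infiltrating macrophage markers had 4 of 16 higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.797 and adjusted p = 0.923 with an estimated correlation). Examples were Ear2 at 1.13 ± 0.06 and Ccr2 at -0.70 ± 0.06, and 2 of the 4 higher and 2 of the 5 lower markers kept their call in the same way. Liver sinusoidal endothelial markers had 5 of 18 higher and 2 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.528 and adjusted p = 0.826 with an estimated correlation). Examples were Pecam1 at 1.15 ± 0.06 and Bmp2 at -0.78 ± 0.06, and 2 of the 5 higher and 1 of the 2 lower markers kept their call in that way. Neutrophil markers had 2 of 12 lower and 10 that did not pass, the 2 being Mmp8 and Mcemp1 (-0.86 ± 0.06) (the same count adjusted over the list alone, camera adjusted p = 0.193 and adjusted p = 0.475 with an estimated correlation). Cholangiocyte markers had 1 of 9 higher and 1 lower, Epcam (0.53 ± 0.11) and Aqp1 (-0.43 ± 0.06), both lost without any 1 of the 4 arrays (adjusted p up to 0.139 and 0.085; 2 and 1 adjusted over the list alone, camera adjusted p = 0.495 and adjusted p = 0.646 with an estimated correlation).

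Across the 28 lists, 9 were higher and 3 lower by camera with its preset correlation, and 0 with the correlation estimated per list, where 1 list had an unadjusted p under 0.05 (M2-type, 0.0415). The estimated setting also missed the shifted list of the simulated data (adjusted p = 0.0819), so its misses do not argue against a list. Fry, which tests whether a list's genes move one way on balance, called 13 higher and 8 lower. Higher by fry, though not by camera on the same values, were the M1-type (adjusted p = 0.0104), clock (0.0103), matrix (0.0279), proliferation (0.0348) and sinusoidal endothelial (0.0451) lists. Lower by fry only were the Kupffer cell identity (0.0103), lipid mediator (0.0103), neutrophil (0.0103), fatty acid oxidation (0.0382) and cholesterol (0.0433) lists. The B cell list passed by camera but not by fry (0.0518). Of the 150 genes named by rule and tested, 133 passed the threshold. Among those with a fitted difference of at least 2-fold, 57 of 63 kept their call whichever of the 4 arrays was left out, and among those under 2-fold, 27 of 70 did.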

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

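The normexp setting on the median signal was chosen after seeing the data, and the others were planned. Normexp on the mean spot signal, a column not in the scanner output, and a slide term, with only 1 slide, were not run. Of the reported calls tested in both, 87.2% to 100% remained under other normalizations, the stricter filter, the mean of a gene's probes, the variance trend and with marked spots kept, and gene lists, where recomputed, numbered 9 higher and 3 or 4 lower. Of the 133 named genes past the threshold, 98 kept their call under all alternatives but leaving out an array and 82 under all; 132 never turned sign. Normexp on the median signal with quantile normalization gave 276 genes at least 2-fold higher and 87 lower, and the cause was not tested. With no filter on dim probes there were 1087 higher and 972 lower genes, 560 at least 2-fold lower and 0 lists lower; the median of all genes moved from -0.02 to -0.14, and 45616 genes were tested. A variance trend gave 4524 and 4672. Leaving out 1 array gave 882 to 1207 higher, 668 to 1162 lower and 288 to 429 at least 2-fold lower, with fewer samples in the fit. With an estimated correlation 0 lists were higher and 0 lower, and fry called 8 lower. Camera with an estimated correlation also missed the shifted list of the simulated data (adjusted p = 0.0819). The cause was not tested for the others.

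The replicate block gave 1766 higher and 1926 lower genes, and the B cell list (0.0877) did not pass. Among the genes whose calls were lost with it were Il6, Ccl2, Ttr, Insig1, Sqle, Tm7sf2 and Epcam. The replicate numbers gave no sign of pairing the arrays, as the deviations of equal numbers correlated with r = -0.0292 across genes, which are not independent replicates. Noise of single arrays could hide a shared source, so pairing cannot be excluded.

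Among genes called in the reported or the changed setting, signs turned at single probes or probe means. With every probe on its own these were Apoc3 (0.131), Il4ra (0.761), Per2 (0.16), Oasl1 (0.241), Ldha (0.859), Timp2 (0.0337) and Cd247 (0.7). With the mean of a gene's probes they were Il4ra (0.375) and Ldha (0.416), since these genes' probes differ. Sign turns without a call in either setting are not listed. Signal over background limits 196 called genes in the vehicle and 121 in the maresin 1 group to bounds.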

Other observations

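Of what follows, only the test of the spike-in RNAs was set before its result was seen; the gene families and the tests of dendritic cell markers, IL-4-induced genes, Il4, hepatocyte carry-over and technical replication were chosen afterwards.

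Members of several gene families, not tested as groups, passed the threshold. Among the Clec4 C-type lectins, 6 of 9 measured members fell and 3 did not pass: Clec4n (-2.06 ± 0.09), Clec4d (-1.82 ± 0.06), Clec4b1 (-1.76 ± 0.06), Clec4e (-1.24 ± 0.06), Clec4a1 (-1.11 ± 0.08) and Clec4a3 (-0.45 ± 0.08), the last lost without either vehicle array or maresin 1 replicate 2 (adjusted p up to 0.123), Clec4f being among the 3. All 3 measured formyl peptide receptor genes fell, Fpr-rs6 by 1.89 ± 0.07 on the log2 scale. Of 10 Toll-like receptor genes, Tlr2, Tlr13 (-1.12 ± 0.06) and Tlr12 (-0.40 ± 0.06) fell and 7 did not pass, among them Tlr4 (0.10 ± 0.09), and the call of Tlr12 was lost without any 1 of the 4 arrays (adjusted p up to 0.1). The directions of the called members of these families held under every alternative.

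Among 16 CC chemokine genes, 10 rose and 3 fell. Ccl12 (1.87 ± 0.07) and Ccl25 (0.77 ± 0.06) were among those that rose and kept their call whichever array was left out. The rises of Ccl9, Ccl2 and Ccl4 and all 3 decreases (Ccl3, Ccl27a and Ccl1) were lost without at least 1 array. Of 9 genes of the Serpina3 cluster, 8 rose, with Serpina3n at 2.61 ± 0.09 and Serpina3f at 1.91 ± 0.06, and Serpina3k (-0.06 ± 0.12) did not pass. They are close paralogs, and the specificity of their probes was not tested. Genes of retinaldehyde oxidation split: Aldh1a2 (2.17 ± 0.07) rose with Aldh1a3, whereas Aldh1a1 (-0.78 ± 0.06) and Aldh1a7 (at least 1.66-fold lower) fell, the latter call lost without any 1 of the 4 arrays (adjusted p up to 0.0705). Of 11 genes of cell fusion and osteoclast function, 6 rose, and each of the 6 kept its call whichever array was left out: Ocstamp, Car2, Dcstamp (1.66 ± 0.11), the collagen-degrading protease gene Ctsk (1.09 ± 0.06), Itgb3 and Atp6v0d2. Nfatc1, which encodes a regulator of osteoclast formation, fell (-0.60 ± 0.06), and that call was lost without vehicle replicate 1 or maresin 1 replicate 2 (adjusted p up to 0.0593).

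The M2-type genes rose with a median of 1.20, and the spike-in test cannot decide whether array position or labelling yield was a cause. The 7 spike-in RNAs well above background on all arrays differed between groups by at most 0.13. All 7 were higher with maresin 1, with a median of 0.11, so differences of that size depend on the zero that the scaling set. However, values were scaled within each array, which removes a shift common to all spots. The spike-ins also do not report on effects limited to some genes, and position coincided with group. A larger share of dendritic cells stays open. The 13 dendritic markers outside the M2-type list had a median of 0.365 and an SD of 0.824. Their sum lies just below 1.20, a limit set after the values were seen, and that margin is too narrow to decide. Itgax and Batf3 rose by more than 1.20. The most abundant marker, Bst2, was too bright with vehicle to show a small share (levels of 6.99 and 7.07), and the rise could come in part from such cells. An IL-4/STAT6-type signal is a candidate explanation that stays open as a hypothesis: of 10 further genes that IL-4 is known to raise in macrophages and that are on none of the gene lists, 8 rose and 2 did not pass, with a median of 0.781, and 5 of the 8 kept their call whichever array was left out. More Il4 transcript in the cultures is argued against (0.019, with a 95% interval from -0.23 to 0.27), while Il13 was not well above background on any array and the cytokine proteins, the vehicle cultures' handling and other routes by which maresin 1 could act were not tested.

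The hepatocyte transcripts were lower by a median of -0.27. A smaller carry-over of hepatocyte RNA would lower all markers by 1 ratio, whereas lower transcription within the cultured cells, which was not tested, need not. The 2 cannot be told apart here, since the SD across the 18 markers, 0.17, was larger than their SE allow (heterogeneity p = 4.25e-08, chi-squared approximation over genes that are not independent) but no larger than the spread of 0.212 between probes of the 6 markers with several probes. That spread is the root mean square of each marker's probe range, divided by the square root of 2. It includes Apoc3, whose probes ran from -0.48 to 0.13. Trf, the most abundant marker, had levels of 3.70 and 3.59, and 1 of the 22 listed markers, Hp, is also on the monocyte list. The Percoll layer named in the labels is a step meant to remove hepatocytes.

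A large share of the genes tested (24%) passed the threshold with 2 arrays per group. Technical replicates with too small a spread for separate cultures may be the reason. Over 272 probes spotted 10 times, the median squared ratio of array differences to spot noise was 1.98 between the vehicle arrays and 3.32 between the maresin 1 arrays, where spot noise alone gives 0.455, and 8.78 to 14.8 between groups. Arrays of a group thus differed by more than their spots did, but labelling and hybridization add noise that spots do not show, so technical replicates and separate cultures cannot be told apart without a pair of arrays known to come from separate cultures.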
